A study of Rattus norvegicus with 14 samples.

How the data were processed

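Gene expression was measured in liver of male F344 rats, an inbred laboratory strain, on Affymetrix Rat Gene ST 1.0 arrays, 1-colour oligonucleotide arrays that probe the whole length of a transcript. Per the labels' protocols, livers were fixed in formalin and embedded in paraffin, regions were isolated from stained sections by laser capture microdissection, and RNA was amplified and biotin-labelled from 150 ng of total RNA with a kit made for such fixed tissue. The 14 arrays came from 12 animals in 4 groups of 3 animals. In the foci groups the captured regions were persistent lesions positive for the placental form of glutathione S-transferase (GSTP), per the labels, so the gene of that marker, Gstp1, is no finding between foci and other liver. The replicate was the animal. Rapamycin animal 3 was run on 3 arrays, of which a pair used the same RNA and the last a new laser capture, per the labels. Per the series' design text, the submitters averaged the arrays of this animal after clustering set it apart from its group, and found it in place by the other parameters they measured.

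The deposited table held 28826 probe sets in 14 columns, and its values were array intensities on a linear scale, from 2.143 to 14037.8. Partek 6.6 and RMA, the robust multi-array average method of background correction, normalization and probe summary, are named in the submitters' processing notes, with no role or order. A background step or normalization setting beyond that name is not given in the sources used here. The design fixed beforehand had assumed log2 values. Since the deposited intensity values were linear, log2 was taken here with no pseudocount, and the arrays of rapamycin animal 3 were averaged on the log2 scale into 1 value. No depth applies to arrays, and their number limits the precision. Every column of per-sample values was used.

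Gene symbols came from the platform annotation given for the probe sets. Of the probe sets, 15209 had 1 gene symbol, 306 had several and 13311 had none. Probe sets with several symbols or with none were used only where every probe set was taken. For the 494 genes with more than 1 probe set, the probe set with the highest mean over the 12 animals was taken, which left 14497 genes. In 105 of those 494 genes at least 1 pair of probe sets correlated below 0 over the animals, so their value depends on that choice. Through Entrez identifiers 14471 genes were matched to a table of the rat assembly GRCr8, which was used for names only and updated 0 symbols.

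Tests were made in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, 2-sided), and tables were read with the package data.table, version 1.17.8. A single fit held the group means of all 12 animals, so that the groups shared 1 estimate of the spread with 8 residual and 6.38 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. The 6 contrasts were placebo foci, rapamycin foci and AAF/PH liver against normal liver, both kinds of foci against AAF/PH liver, and rapamycin foci against placebo foci. Log2 differences are given ± the standard error of the fit, and intensities as geometric means of 3 animals. For 27 gene lists, camera with a preset inter-gene correlation of 0.01 asked whether the members moved more than the other genes, with Benjamini-Hochberg adjustment over the 27 lists of a contrast. Camera with an estimated correlation and fry stood beside it, and members were also counted when adjusted over the list alone. The lists were focus and liver tumour markers, NRF2, aryl hydrocarbon receptor, p53 and ATF4 target genes, biliary and oval cell markers, mature hepatocyte genes, cytochrome P450 and sex-biased hepatocyte genes, bile acid synthesis and transport, pericentral Wnt-responsive genes, cell cycle, ribosomal protein, ribosome biogenesis, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, glycolysis, autophagy and lysosome genes, mTOR pathway components, acute phase genes, interferon-stimulated genes, and genes of stellate cells and matrix, macrophages, lymphocytes, neutrophils, endothelium and red cells.

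The groups, contrasts, tests, gene lists, alternative analyses and the rule for named genes were fixed before the data were examined. Under that rule each contrast names Gstp1 and, among called genes whose animals did not overlap between the groups, the 10 largest rises and 10 largest falls (5 and 5 for foci against AAF/PH liver and for rapamycin foci against normal liver). Where fewer than 5 passed in a direction, the genes of largest moderated t up to 5 are given as values. Each list described names up to 4 members of smallest p, and rapamycin against placebo also names Mtor and Ddit4. Symbols of predicted genes, olfactory and vomeronasal receptors, microRNAs and pseudogenes were passed over. Genes named outside this rule are said to have been chosen after their values were seen.

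The calculations were tested on simulated data of 14497 genes with 200 changed genes in each contrast. For genes changed 2-fold, 68% were recovered in rapamycin against placebo foci, 70% in placebo foci, 76% in rapamycin foci and 61% in AAF/PH liver against normal liver, 67% in placebo foci and 71% in rapamycin foci against AAF/PH liver. For genes changed 4-fold the recovery was 100%, 100%, 98%, 100%, 100% and 100% in the same order. The false share of calls was 5.1%, 5.6%, 5.4%, 4.2%, 5.6% and 2.8%. In the simulation for rapamycin against placebo foci, the list made to shift was called and 0 of the other lists were, and 0 genes were called in 3 unchanged comparisons. The simulated noise was independent between genes and animals and had the same spread in every group. It held no animal set apart from its group, as rapamycin animal 3 was, and no genes that vary together. Recovery in the real rapamycin contrasts and false calls of lists can therefore not be read from it.

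The alternative analyses fixed in advance were leaving out the dimmest 30% of genes, testing every probe set, quantile normalization, median centring, an intensity trend with robust eBayes, no moderation of variances, fitting only the groups compared, array quality weights, other treatments of the arrays of rapamycin animal 3 (a linear average, its first array, its last array, 14 arrays with the animal as a random block), the replicate number as a block, a 2-fold minimum, an estimated inter-gene correlation, and leaving out each animal in turn. For similarity and overlap they were Spearman correlation, the 5% most variable genes and an adjusted p under 0.01. Chosen after the data were seen were a covariate for background (the median of olfactory receptor genes, which liver is not expected to express), quantile normalization without rapamycin animal 3, and leaving that animal out of the shared spread. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.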

Results

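Transcript levels were measured in 12 male F344 rats in 4 groups of 3 animals. Normal liver came from unmanipulated adults. AAF/PH liver came from rats that carried a 2.5 mg pellet of 2-acetylaminofluorene (AAF), a carcinogen that blocks the division of hepatocytes, with a release time of 14 days. The pellet was placed on day 1 and partial hepatectomy followed on day 7. The livers were taken on day 14, when oval cells, progenitor cells of the liver, proliferate. Foci came from the Solt-Farber model of chemical hepatocarcinogenesis. Diethylnitrosamine was given at 200 mg/kg on day 1, an AAF pellet on day 14, and partial hepatectomy on day 21 together with a 21-day pellet of placebo or of rapamycin at 2.5 mg/kg per day. Rapamycin inhibits mTOR, a kinase that couples nutrients to cell growth. Persistent lesions that stained for GSTP were captured on day 70, so that the comparison of both kinds of foci addresses whether an effect of mTOR inhibition lasts. The median intensity over all probe sets ran from 19.84 to 25.37 over the 14 arrays. The spread of the signal differed between them. The interquartile range of log2 intensity over genes was 1.57 to 1.71 on the 3 arrays of rapamycin animal 3 and 1.98 to 2.80 on the 11 others.

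In foci of placebo-treated rats, Akr1b8, Slc7a11 and Nqo1 were among the largest rises over normal liver and Aox3, Stac3 and Cyp2c11 among the largest falls. Gstp1 (probe set 10727429), the marker by which the lesions were chosen and therefore no finding, stood at a geometric mean intensity of 4023 against 109.6, a log2 difference of 5.20 ± 0.27 (standard error, n = 3 animals per group, limma adjusted p = 4.34e-08). Akr1b8 (probe set 10854406), an aldo-keto reductase, rose by 5.29 ± 0.46. Slc7a11, the cystine importer that feeds glutathione synthesis, rose by 5.11 ± 0.53, and Nqo1, a quinone reductase, by 4.21 ± 0.45. Akr7a3, an aflatoxin aldehyde reductase, reached an intensity of 2000 against 92.36, and Defb1, an antimicrobial peptide, 359 against 14.89. Car2, Pla2g7, Ccdc92 and the exporter gene Abcc3 also rose, by 4.46, 3.94, 3.84 and 3.75. In the other direction, Aox3 (probe set 10923432), an aldehyde oxidase, had a log2 difference of -4.70 ± 0.22 (adjusted p = 1.8e-08) and Stac3, an adaptor protein best known from muscle, -4.47 ± 0.18 (adjusted p = 6.09e-09). Cyp2c11, the main male-specific cytochrome P450 of rat liver, fell by 4.25 ± 0.43, from an intensity of 1713 to 89.96. Car3, Dhrs7l1, Cdh17, Inmt, Cyp3a23-3a1, Avpr1a and Cyp3a2 fell too, with differences of -4.05, -4.04, -3.94, -3.88, -3.79, -3.73 and -3.56. Of 14497 genes, limma called 1192 at an adjusted p under 0.05, 412 higher and 780 lower, and 756 of them differed at least 2-fold. The groups did not overlap in 30.5% of all genes, where chance gives 10%. The count was 606 without normal liver animal 1, 688 without normal liver animal 3, 675 without placebo animal 1 and 763 without placebo animal 2.

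Targets of NRF2, the transcription factor of the response to electrophiles, rose together in placebo foci. The lesions were chosen by GSTP, so genes whose levels go with Gstp1 are not independent of that choice. This limit holds for every comparison of foci with other liver. Of 22 measured members, 14 rose and 0 fell (16 and 0 adjusted over the list alone), with a median log2 difference of 1.48 (camera adjusted p = 1.61e-16, and adjusted p = 0.13 with an estimated correlation). Among 15 focus and liver tumour markers, a list that holds Gstp1 itself, 8 rose and 2 fell (9 and 2 adjusted over the list alone; median 1.20, adjusted p = 1.95e-08). Aldh3a1, an aldehyde dehydrogenase of hepatic tumours, rose by 2.79 ± 0.18, while Cdh17, a cadherin of gut and liver, was among the falls above. Biliary and oval cell markers rose in 7 members and fell in 1 of 21 (10 and 1 adjusted over the list alone; median 0.46, adjusted p = 6.48e-07). Cd24, a surface protein of progenitor cells, rose by 2.39 ± 0.30, Sox4, a transcription factor of duct development, by 1.57 ± 0.25 and Tnfrsf12a, the receptor of the cytokine TWEAK, by 0.99 ± 0.17, whereas Onecut1, a factor of hepatocyte and duct development, fell by 1.72 ± 0.26. Of 36 cell cycle genes, 7 rose and 0 fell (23 and 0 adjusted over the list alone; median 0.51, adjusted p = 1.26e-11). They included the mitotic cyclins Ccnb2, by 1.33 ± 0.18, and Ccnb1, by 1.20 ± 0.25, and Rrm2, a subunit of ribonucleotide reductase, by 2.03 ± 0.41. ATF4 targets, genes of the amino acid response, rose in 9 and fell in 2 of 20 (10 and 3 adjusted over the list alone; median 0.68, adjusted p = 0.00188, and adjusted p = 0.173 with an estimated correlation). Pycr1, of proline synthesis, rose by 1.27 ± 0.21, but Atf5, itself a stress transcription factor, fell by 1.52 ± 0.18 and Cth, of cysteine synthesis, by 2.08 ± 0.34.

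Functions of the mature hepatocyte were lower in placebo foci. Mature hepatocyte genes fell in 15 of 26 members and rose in 0 (20 and 0 adjusted over the list alone; median -1.16, camera adjusted p = 9.45e-13, and adjusted p = 0.181 with an estimated correlation). Gnmt, the glycine methyltransferase that sets the supply of methyl groups, fell by 2.51 ± 0.23, Agxt, of glyoxylate removal, by 2.23 ± 0.24 and Fbp1, of gluconeogenesis, by 1.42 ± 0.28. Cytochrome P450 and sex-biased genes fell in 11 and rose in 1 of 16 (13 and 1 adjusted over the list alone; median -1.39, adjusted p = 9.45e-13, and adjusted p = 0.13 with an estimated correlation). Cyp3a9 stood at -3.02 ± 0.26 (standard error) and Cyp2a2 at -2.56 ± 0.29. Bile acid synthesis and transport fell in 9 of 17 and rose in 0 (11 and 1 adjusted over the list alone; median -1.21, adjusted p = 8.51e-10, and adjusted p = 0.13 with an estimated correlation). Its members included Slc27a5, which couples bile acids to coenzyme A and fell from an intensity of 831.4 to 80.12, and Cyp8b1, the sterol 12-hydroxylase, from 623.6 to 176.4. Pericentral Wnt-responsive genes fell in 4 and rose in 1 of 11 (5 and 1 adjusted over the list alone; median -0.27, adjusted p = 0.00397, and adjusted p = 0.181 with an estimated correlation). Oat, Notum and Lect2 fell by 2.99, 1.43 and 1.78, while the ammonium transporter gene Rhbg, also of this zone, rose by 1.67 ± 0.26.

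Lipid genes were lower as well. Cholesterol synthesis genes fell in 8 of 18 and rose in 0 (14 and 0 adjusted over the list alone; median -1.14, camera adjusted p = 8.88e-09, and adjusted p = 0.243 with an estimated correlation). Pmvk, of the mevalonate pathway, fell by 1.15 ± 0.22 and the sterol reductase gene Hsd17b7 by 0.97 ± 0.20. Fatty acid synthesis genes fell in 5 of 18 and rose in 0 (7 and 1 adjusted over the list alone; median -0.94, adjusted p = 0.000196, and adjusted p = 0.393 with an estimated correlation). Dgat2, of triglyceride synthesis, fell by 1.28 ± 0.23. Fatty acid oxidation genes fell in 9 of 20 and rose in 0 (10 and 0 adjusted over the list alone; median -0.84, adjusted p = 4.6e-11, and adjusted p = 0.173 with an estimated correlation). Pdk4, which restrains glucose oxidation, fell by 2.88 ± 0.34 and Cyp4a3, a fatty acid hydroxylase, by 2.51 ± 0.22. Acute phase genes fell in 8 of 19 and rose in 0 (12 and 0 adjusted over the list alone; median -0.71, adjusted p = 1.89e-07, and adjusted p = 0.173 with an estimated correlation). Itih4 fell by 1.56 ± 0.24, Apcs by 1.36 ± 0.22 and the fibrinogen gene Fga by 1.16 ± 0.20. Glycolysis genes rose in 3 and fell in 1 of 17 (4 and 1 adjusted over the list alone; median 0.36, adjusted p = 0.0378, and adjusted p = 0.384 with an estimated correlation). That call was lost without normal liver animal 2 (adjusted p = 0.0682) and without placebo animal 3 (median 0.15, adjusted p = 0.166). No autophagy and lysosome gene of 29 passed (0 adjusted over the list alone), but the list stood lower (median -0.20, adjusted p = 0.0285, and adjusted p = 0.707 with an estimated correlation). This call was lost without placebo animal 2 (median -0.13, adjusted p = 0.123) and after quantile normalization.

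Markers of other cell types were tested as well. Stellate cell and matrix genes rose in 4 of 25 and fell in 0 (4 and 0 adjusted over the list alone; median 0.30, camera adjusted p = 0.000693, and adjusted p = 0.342 with an estimated correlation). Lox, which crosslinks collagen, rose by 1.00 ± 0.19 and Col4a1, a basement membrane collagen, by 0.84 ± 0.17. No lymphocyte gene of 22 passed (0 adjusted over the list alone), while the list stood higher (median 0.25, adjusted p = 0.00188, and adjusted p = 0.243 with an estimated correlation). The macrophage list had a median of 0.20 and a mean of -0.05 (adjusted p = 0.976), with 1 rise and 2 falls among 21 (1 and 4 adjusted over the list alone). Marco, a scavenger receptor of Kupffer cells, fell by 1.82 ± 0.23. In the erythroid list 0 of 8 rose and 2 fell (0 and 2 adjusted over the list alone; median -0.10, adjusted p = 0.166), both haemoglobin genes, Hbb by 1.40 ± 0.26 and Hbb-b1 by 1.18 ± 0.24. Endothelial genes rose in 1 and fell in 2 of 18 (1 and 3 adjusted over the list alone; median -0.22, adjusted p = 0.0631). The lists of aryl hydrocarbon receptor targets (median 0.18, adjusted p = 0.0812, 2 of 7 higher and 1 lower, the same adjusted over the list alone), interferon-stimulated genes (0.16, 0.15, 1 of 25 higher and 0 lower, the same adjusted over the list alone) and ribosomal proteins (0.00, 0.337, 1 of 66 higher and 0 lower, and 0 and 0 adjusted over the list alone) were not called. Nor were p53 targets (0.20, adjusted p = 0.228), ribosome biogenesis genes (0.04, adjusted p = 0.57), mTOR pathway components (-0.18, adjusted p = 0.281) and neutrophil genes (0.21, adjusted p = 0.246), with 0 members past the threshold in each.

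**Figure D1:**
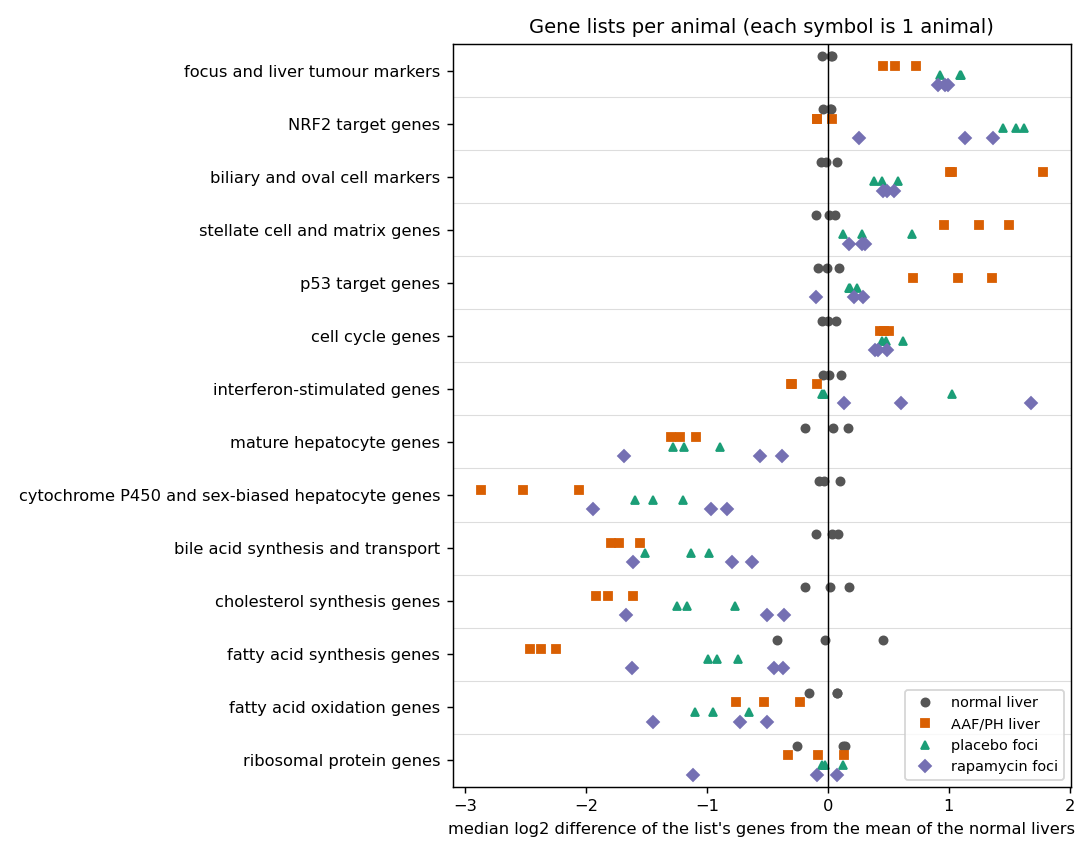
Median log2 difference of the measured members of 14 gene lists from the mean of the normal livers (x axis, log2 units), with a symbol for each of the 12 animals and a colour and shape for each group. NRF2 target genes stood at 1.45 to 1.62 in the placebo foci but at 1.13, 1.37 and 0.26 in the rapamycin foci, while stellate cell and matrix genes stood at 0.96 or above in every AAF/PH liver.

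AAF/PH liver, the setting of oval cell proliferation, showed the widest change from normal liver among the comparisons made, with the multidrug exporter and collagen genes among the largest rises and a male-specific P450 and desaturase genes among the largest falls. Abcb1b (probe set 10853324), the exporter, rose by 4.75 ± 0.34 (standard error, n = 3, limma adjusted p = 5.06e-07), from an intensity of 44.13 to 1187. Collagen genes rose, Col1a1 by 3.55 ± 0.45 and Col1a2 by 2.68 ± 0.36, as did Afp, the fetal serum protein, by 2.90 ± 0.36. Dmbt1, a mucin-like protein of ducts, rose by 3.19 ± 0.25, the laminin gene Lama5 by 3.13 ± 0.21 and Igfbp1, which binds insulin-like growth factors, by 2.97 ± 0.50, and Pln, Bex4 and Car2 were also among the 10 largest rises. Cyp2c11 (probe set 10715211) fell by 7.00 ± 0.43, from an intensity of 1713 to 13.34 (adjusted p = 3.29e-07). The fatty acid desaturase genes Fads2 and Fads1 fell by 5.73 ± 0.41 and 5.24 ± 0.38, Slc10a1, the bile acid importer, by 5.02 ± 0.34 and Otc, of the urea cycle, by 4.90 ± 0.42. Serpina3c, Sult1c3, Sult2a1, Dhrs7l1 and Serpina4 completed the 10 largest falls, with Serpina3c at -5.88 and Sult1c3 at -5.39. Gstp1 had a log2 difference of 0.73 ± 0.27 and did not pass (adjusted p = 0.0717). Limma called 2900 of 14497 genes, 1093 higher and 1807 lower, and 1558 differed at least 2-fold. The groups did not overlap in 49.6% of all genes, where chance gives 10%. The share of calls that were higher was 37.7%, against 522 of 2614 calls after median centring, but 4226 higher and 3770 lower with array quality weights and 1752 higher and 1630 lower with the background covariate, so the direction of the majority depended on the setting. Centring moved the median difference of all genes from 0.12 to -0.08 and quantile normalization moved it to 0.01. The count was 1552 without normal liver animal 1, 1784 without normal liver animal 3 and 1798 without AAF/PH animal 2.

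Biliary and oval cell markers rose in 17 and fell in 1 of 21 in AAF/PH liver (17 and 1 adjusted over the list alone; median 1.39, camera adjusted p = 9.04e-10), with Cd24 at 2.54 ± 0.30, Tnfrsf12a at 1.62 ± 0.17 and the tetraspanin gene Tspan8 at 1.57 ± 0.17. Stellate cell and matrix genes rose in 18 of 25 and fell in 0 (21 and 0 adjusted over the list alone; median 1.30, adjusted p = 8.66e-13, and adjusted p = 0.121 with an estimated correlation). Col4a1 rose from an intensity of 40.89 to 250.0, Col3a1 from 70.3 to 437.4 and Tagln, an actin-binding protein of contractile cells, from 61.11 to 323.5. Targets of p53, the responder to DNA damage, rose in 10 of 14 and fell in 0 (10 and 0 adjusted over the list alone; median 0.95, adjusted p = 3.95e-06, and adjusted p = 0.157 with an estimated correlation). Cdkn1a, the inhibitor of cyclin-dependent kinases, rose from 137.8 to 740.1, Mdm2, the ligase that degrades p53, by 2.06 ± 0.27 and the death receptor gene Tnfrsf10b by 2.03 ± 0.23. Cell cycle genes rose in 10 of 36 and fell in 0 (13 and 0 adjusted over the list alone; median 0.49, adjusted p = 8.72e-07, and adjusted p = 0.101 with an estimated correlation). Mcm2, a replication helicase subunit, rose by 0.93 ± 0.18. Focus and tumour markers rose in 4 and fell in 2 of 15 (10 and 2 adjusted over the list alone; median 0.73, adjusted p = 0.00998, and adjusted p = 0.197 with an estimated correlation). Cd44, a hyaluronan receptor, rose by 2.67 ± 0.26, and Spink1, a trypsin inhibitor, fell by 2.52 ± 0.25. NRF2 targets went both ways, 6 higher and 3 lower of 22 (7 and 4 adjusted over the list alone; median -0.10, mean -0.01, adjusted p = 0.981). Cbr1, a carbonyl reductase, stood at 0.99 ± 0.21 and Gclm, of glutathione synthesis, at -1.81 ± 0.39.

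Cytochrome P450 and sex-biased genes fell in 13 and rose in 2 of 16 in AAF/PH liver (13 and 2 adjusted over the list alone; median -2.88, camera adjusted p = 8.89e-12, and adjusted p = 0.157 with an estimated correlation). Bile acid genes fell in 14 of 17 and rose in 0 (14 and 0 adjusted over the list alone; median -1.55, adjusted p = 8.01e-12, and adjusted p = 0.121 with an estimated correlation). Mature hepatocyte genes fell in 18 of 26 and rose in 0 (19 and 0 adjusted over the list alone; median -1.19, adjusted p = 5.43e-11, and adjusted p = 0.236 with an estimated correlation). Bhmt, of homocysteine methylation, fell by 3.61 ± 0.31 and the apolipoprotein gene Apoc3 by 3.30 ± 0.30. Cholesterol synthesis genes fell in 16 of 18 and rose in 0 (18 and 0 adjusted over the list alone; median -1.86, adjusted p = 8.66e-13, and adjusted p = 0.197 with an estimated correlation). Sc5d fell by 3.08 ± 0.38 and Cyp51 by 2.52 ± 0.35. Fatty acid synthesis genes fell in 14 and rose in 1 of 18 (16 and 1 adjusted over the list alone; median -2.41, adjusted p = 1.41e-13, and adjusted p = 0.168 with an estimated correlation). Scd, the stearoyl desaturase, stood at -4.58 ± 0.44 and Thrsp, a lipogenic nuclear protein, at -4.67 ± 0.54.

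Smaller shifts in AAF/PH liver were lost both with an estimated correlation and after quantile normalization. Fatty acid oxidation genes fell in 7 and rose in 2 of 20 (9 and 3 adjusted over the list alone; median -0.40, camera adjusted p = 0.00366, and adjusted p = 0.551 with an estimated correlation). Ehhadh, a peroxisomal enzyme of this list, fell by 3.38 ± 0.32 (standard error). Autophagy and lysosome genes fell in 9 and rose in 1 of 29 (10 and 1 adjusted over the list alone; median -0.48, adjusted p = 0.000295, and adjusted p = 0.551 with an estimated correlation). The mTOR components fell in 2 and rose in 1 of 20, the same adjusted over the list alone (median -0.44, adjusted p = 0.0124, and adjusted p = 0.633 with an estimated correlation). A neutrophil gene of 12 rose (0 adjusted over the list alone; median 0.46, adjusted p = 0.0162, and adjusted p = 0.517 with an estimated correlation). Lymphocyte genes rose in 5 of 22 (5 adjusted over the list alone; median 0.47, adjusted p = 0.000295, and adjusted p = 0.197 with an estimated correlation). In lists that were not called, the acute phase genes Lcn2 and Orm1 rose by 1.96 ± 0.22 and 1.20 ± 0.21 while Apcs fell by 2.34 ± 0.22, and Hbb-b1 fell by 2.19 ± 0.24. The pericentral list had a median of 0.10 and a mean of -0.20 (adjusted p = 0.439) and the endothelial list a median of 0.006 and a mean of -0.03 (adjusted p = 0.981).

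Foci of both treatments were set against AAF/PH liver, whose rats received AAF and partial hepatectomy but no diethylnitrosamine. The times differed as well. AAF/PH liver was taken on day 14 after hepatectomy on day 7, and foci on day 70 after hepatectomy on day 21. Foci were also captured as lesions positive for GSTP. Carcinogen, time since AAF and surgery, and the choice of lesions cannot be told apart in these comparisons. In placebo foci Fads2 was higher by 4.79 ± 0.41 (standard error, n = 3, limma adjusted p = 1.66e-05), Slc7a11 by 4.72 ± 0.53, Serpina3c by 4.71 ± 0.48 and Gclm by 4.37 ± 0.39, and Gstp1, the gene of selection, by 4.47 ± 0.27. Pln, Afp, Crot, Npy and Cdh17 were the 5 largest falls, with Afp at an intensity of 49.35 against 449.7. The call of Npy was lost without placebo animal 1. In rapamycin foci Serpina3c was higher by 5.03 ± 0.48, Fads2 by 4.89 ± 0.41, Scd by 4.39 ± 0.44, Fads1 by 4.31 ± 0.38 and Cyp2c11 by 4.21 ± 0.43, and Gstp1 by 4.10 ± 0.27. Pln, Abcb1b, Afp, Npy and Tagln fell most, Abcb1b from 1187 to 116.1. Limma called 608 genes for placebo foci, 380 higher and 228 lower, and 581 for rapamycin foci, 310 higher and 271 lower. Which direction held more calls changed with the setting, with 832 higher and 921 lower for placebo foci with the background covariate. For rapamycin foci there were 545 higher and 616 lower after quantile normalization, 114 and 162 without moderation, and 172 and 247 without rapamycin animal 2. For placebo foci the count was 355 without AAF/PH animal 2, 330 without AAF/PH animal 3, and 339, 369 and 367 without placebo animals 1, 2 and 3. For rapamycin foci it was 359 without AAF/PH animal 2, 297 without AAF/PH animal 3, 338 without rapamycin animal 1 and 2058 without rapamycin animal 3, where 73.2% of calls were higher.

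Against AAF/PH liver, NRF2 targets were higher in 15 of 22 members in placebo foci (16 adjusted over the list alone; median 1.61, camera adjusted p = 1.37e-19, and adjusted p = 0.115 with an estimated correlation). In rapamycin foci 10 were higher (14 higher and 3 lower adjusted over the list alone; median 1.02, adjusted p = 1.36e-11, and adjusted p = 0.177 with an estimated correlation), and leaving out rapamycin animal 2 gave a median of 0.66. Nqo1 rose by 4.36 ± 0.45 and 3.08 ± 0.45 in the 2 kinds of foci and Gclc, the catalytic subunit of glutathione synthesis, by 3.39 ± 0.37 and 2.76 ± 0.37. Fatty acid synthesis genes were higher in 10 of 18 in both (15 and 17 adjusted over the list alone; medians 1.53 and 1.35, adjusted p = 2.92e-18 and 4.66e-22, and adjusted p = 0.115 and 0.109 with an estimated correlation). Stellate cell and matrix genes fell in 13 of 25 in placebo foci (20 adjusted over the list alone; median -1.04, adjusted p = 4.96e-18, and adjusted p = 0.103 with an estimated correlation). They fell in 15 in rapamycin foci (22 adjusted over the list alone; adjusted p = 1.28e-26, and adjusted p = 0.0323 with an estimated correlation). Col4a1 stood at -1.77 ± 0.17 and -2.06 ± 0.17 in the 2 kinds of foci. Targets of p53 fell in 6 of 14 in both (8 and 10 adjusted over the list alone; median -0.65 in placebo foci, adjusted p = 9.19e-09 and 3.13e-12, and adjusted p = 0.115 and 0.0473 with an estimated correlation). Cdkn1a fell by 2.58 ± 0.34 (standard error) and 2.64 ± 0.34. Biliary and oval cell markers fell in 5 and 7 of 21 (10 and 11 adjusted over the list alone; medians -0.49 and -0.68, adjusted p = 2.08e-05 and 1.64e-10, and adjusted p = 0.069 and 0.00604 with an estimated correlation). Tspan8 fell by 1.25 ± 0.17 and 1.28 ± 0.17. Interferon-stimulated genes were higher in 1 of 25 in placebo foci (1 adjusted over the list alone; median 0.55, and 0.24 without placebo animal 3; adjusted p = 4.81e-06, and adjusted p = 0.468 with an estimated correlation). They were higher in 8 in rapamycin foci (14 adjusted over the list alone; median 1.25, and 0.73 without rapamycin animal 1; adjusted p = 2.86e-15, and adjusted p = 0.177 with an estimated correlation). The antiviral genes Mx2 and Oasl stood at 2.38 ± 0.47 and 1.88 ± 0.36.

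Lists of other cell types than hepatocytes also stood lower in foci than in AAF/PH liver. Macrophage genes fell in 1 of 21 in placebo foci (4 adjusted over the list alone; median -0.19, camera adjusted p = 0.00742, and adjusted p = 0.586 with an estimated correlation), a call lost without placebo animal 2 (adjusted p = 0.0734), and the median was -0.36 without placebo animal 3. They fell in 4 in rapamycin foci (1 higher and 8 lower adjusted over the list alone; adjusted p = 4.53e-09, and adjusted p = 0.198 with an estimated correlation), with a median of -0.29 without rapamycin animal 3. Marco fell by 1.99 ± 0.23 (standard error) in placebo foci and 1.53 ± 0.23 in rapamycin foci. Endothelial genes stood lower in both (medians -0.21 and -0.34, adjusted p = 0.0291 and 0.000742, and adjusted p = 0.586 and 0.356 with an estimated correlation), with 0 and 1 of 18 members past the threshold (0 and 1 adjusted over the list alone). In rapamycin foci that call was lost without rapamycin animal 3 (-0.19, adjusted p = 0.141), and in placebo foci without AAF/PH animals 1 or 3 or placebo animals 1 or 2. Lymphocyte (median -0.18, adjusted p = 0.0449, and adjusted p = 0.528 with an estimated correlation) and neutrophil genes (median -0.22, adjusted p = 0.0255, and adjusted p = 0.528 with an estimated correlation) were called lower in placebo foci only, with 0 members past the threshold (0 and 1 adjusted over the list alone). The lymphocyte call was lost without AAF/PH animals 1 or 2 or placebo animals 1 or 2, and the neutrophil call without AAF/PH animal 1 (-0.13) or placebo animal 3, with a median of -0.38 without AAF/PH animal 3.

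Lists of hepatocyte functions ran in both directions between foci and AAF/PH liver. P450 genes were higher in 7 and lower in 2 of 16 in both kinds of foci (9 and 11 higher adjusted over the list alone). Their medians were 0.78 in placebo foci (camera adjusted p = 1.05e-05, and adjusted p = 0.4 with an estimated correlation) and 1.17 in rapamycin foci (adjusted p = 1.63e-09, and adjusted p = 0.177 with an estimated correlation). Slc10a1 rose by 3.80 ± 0.34 (standard error) in rapamycin foci, and Otc by 3.91 ± 0.42 in placebo foci and 3.76 ± 0.42 in rapamycin foci. Cholesterol synthesis genes were higher in 5 and 6 of 18 (8 and 12 adjusted over the list alone; medians 0.72 and 0.99, adjusted p = 9.68e-08 and 4.8e-11, and adjusted p = 0.4 and 0.198 with an estimated correlation). Acute phase genes ran the other way in placebo foci, with 1 higher and 4 lower of 19 (1 and 7 adjusted over the list alone; median -0.45, adjusted p = 0.000464, and adjusted p = 0.4 with an estimated correlation), where Orm1 fell by 1.58 ± 0.21 and Lcn2 by 1.55 ± 0.22.

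Mature hepatocyte genes went both ways between placebo foci and AAF/PH liver, from -2.02 to 3.91, with 7 higher and 2 lower of 26 (10 and 4 adjusted over the list alone; median 0.11, camera adjusted p = 0.0255, and adjusted p = 0.633 with an estimated correlation). The call was lost without AAF/PH animal 3 (median 0.04, adjusted p = 0.0743), and the medians over left-out animals ran up to 0.22, without AAF/PH animal 1. In rapamycin foci 8 were higher and 1 lower (11 and 3 adjusted over the list alone; mean 0.49, adjusted p = 4.11e-05, and adjusted p = 0.449 with an estimated correlation), with medians of 0.14, 0.10 and 0.74 without rapamycin animals 1, 2 and 3. Fatty acid oxidation genes stood lower in both (medians -0.13 and -0.13, adjusted p = 0.0272 and 0.0399, and adjusted p = 0.593 and 0.669 with an estimated correlation), with 3 higher and 6 lower of 20 in placebo foci (4 and 7 adjusted over the list alone) and 2 and 5 in rapamycin foci (3 and 7 adjusted over the list alone). Both calls were lost without AAF/PH animal 3 (medians 0.04 and 0.02), that of placebo foci also without placebo animal 2 (-0.07), and that of rapamycin foci also without AAF/PH animal 1 (-0.10) and rapamycin animal 3 (0.19). Pericentral genes stood lower in placebo foci (0 higher and 2 lower of 11, 0 and 4 adjusted over the list alone, median -0.19, adjusted p = 0.0272, and adjusted p = 0.4 with an estimated correlation), a call lost without AAF/PH animal 1 (-0.05) and without placebo animal 2 (-0.14). The aryl hydrocarbon receptor list had medians of -0.13 and -0.26 but means of 0.59 and 0.29 and was not called (adjusted p = 0.529 and 0.881), and the acute phase list had a median of 0.03 and a mean of -0.12 in rapamycin foci (adjusted p = 0.67).

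**Figure D2:**
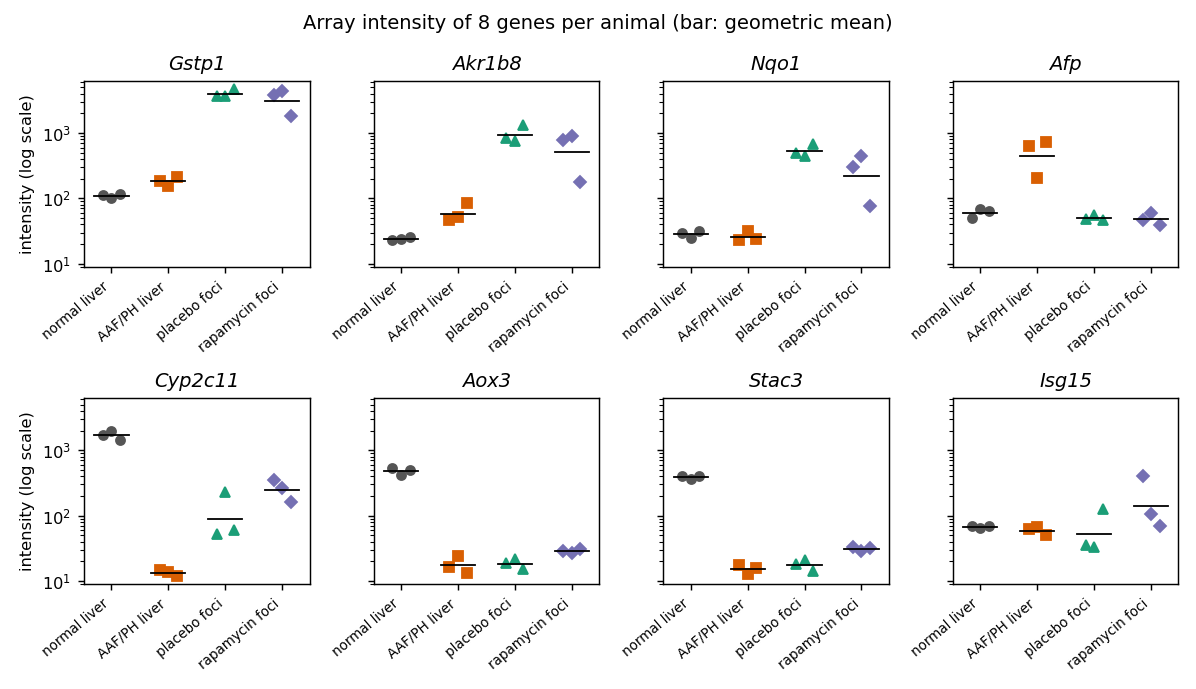
Intensity of 8 genes (y axis, array intensity on a log scale) in the 4 groups, with a symbol for each of the 12 animals and a bar at each group's geometric mean. Nqo1 stood at 446.6 to 669.3 in placebo foci and at 306, 447.2 and 76.95 in rapamycin foci, and Isg15 at 399.1 in rapamycin animal 1.

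The leading genes of rapamycin foci against normal liver were all among the 10 largest rises and 10 largest falls of placebo foci. Akr1b8 rose by 4.38 ± 0.46 (standard error, n = 3, limma adjusted p = 0.000103), Akr7a3 by 3.91 ± 0.33, Slc7a11 by 3.48 ± 0.53 and Car2 by 3.39 ± 0.54, and Gstp1, the gene of selection, by 4.83 ± 0.27. The largest falls were Aox3 at -4.08 ± 0.22, Stac3 at -3.63 ± 0.18, Cdh17 at -3.52 ± 0.32, Inmt at -3.50 ± 0.19 and Dhrs7l1 at -3.38 ± 0.44. Limma called 947 genes, 232 higher and 715 lower, and 566 differed at least 2-fold. The share of calls that were higher was 24.5%, against 87 of 868 calls after median centring, which moved the median difference of all genes from 0.07 to -0.10. It was 41.8% without rapamycin animal 3 and 43.3% after quantile normalization without that animal. The count was 224 without normal liver animal 1, 284 without normal liver animal 3 and 2051 without rapamycin animal 2. It was 289 without moderation of variances and 210 when only these groups were fitted. The standard errors above rest on the spread shared by all groups and do not show that of rapamycin foci alone. For Akr1b8 the SD was 1.297 in rapamycin foci and 0.089 in normal liver. For Aox3 it was 0.092 and 0.198.

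NRF2 targets rose in 11 of 22 members and fell in 0 in rapamycin foci against normal liver (12 and 0 adjusted over the list alone; median 0.85, camera adjusted p = 5.83e-08, and adjusted p = 0.314 with an estimated correlation). Without rapamycin animal 3 the median was 1.35. Nqo1 rose by 2.94 ± 0.45 (standard error) and Abcc3 by 3.14 ± 0.31. Focus and tumour markers rose in 7 and fell in 2 of 15 (10 and 2 adjusted over the list alone; median 0.73, adjusted p = 1.42e-06). Biliary and oval cell markers rose in 5 and fell in 1 of 21 (5 and 1 adjusted over the list alone; median 0.43, adjusted p = 0.000112). Cell cycle genes rose in 3 and fell in 0 of 36 (12 and 0 adjusted over the list alone; median 0.44, adjusted p = 5.83e-08). ATF4 targets rose in 8 and fell in 1 of 20 (9 and 4 adjusted over the list alone; median 0.45, adjusted p = 0.00279, and adjusted p = 0.244 with an estimated correlation), among them Phgdh, of serine synthesis, by 1.30 ± 0.18. Mature hepatocyte genes fell in 6 of 26 and rose in 0 (18 and 0 adjusted over the list alone; median -0.95, adjusted p = 7.16e-09, and adjusted p = 0.314 with an estimated correlation), with a median of -0.48 without rapamycin animal 3. P450 genes fell in 10 of 16 and rose in 0 (13 and 1 adjusted over the list alone; median -1.26, adjusted p = 7.16e-09, and adjusted p = 0.23 with an estimated correlation). Cyp2c11 stood at -2.80 ± 0.43. Fatty acid oxidation genes fell in 10 of 20 and rose in 0 (15 and 0 adjusted over the list alone; median -0.93, and -0.60 without rapamycin animal 3; adjusted p = 7.16e-09, and adjusted p = 0.26 with an estimated correlation). Interferon-stimulated genes rose in 2 of 25 (9 adjusted over the list alone; median 0.87, and 0.37 without rapamycin animal 1; adjusted p = 7.6e-05, and adjusted p = 0.448 with an estimated correlation). Ribosomal protein genes stood lower as a list with 0 of 66 members past the threshold (0 adjusted over the list alone; median -0.36, adjusted p = 0.000351, and adjusted p = 0.601 with an estimated correlation). The call was lost without rapamycin animal 3 (median -0.02, adjusted p = 0.814), while without normal liver animal 2 and rapamycin animal 2 the medians were -0.54 and -0.62. The p53 list had a median of 0.17 and a mean of -0.03 and was not called (adjusted p = 0.782).

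Between foci of rapamycin-treated and placebo-treated rats, the comparison that asks whether the drug left a lasting mark, no gene passed the test. The largest moderated differences were Cyp4a3 (probe set 10878787), a fatty acid hydroxylase induced by PPARα, with an intensity of 897.9 against 360.1, a log2 difference of 1.32 ± 0.22 (standard error, n = 3, limma adjusted p = 0.512), and Atf5 with 719.5 against 363.8, a difference of 0.98 ± 0.18 (adjusted p = 0.521). Inhbe, a liver activin subunit, stood at 0.96 ± 0.20, Stac3 at 0.83 ± 0.18 and the apolipoprotein gene Apoa4 at 0.79 ± 0.19. In the other direction stood the macrophage elastase gene Mmp12 at -1.07 ± 0.22, Tceal9 at -1.53 ± 0.33, the exporter gene Abcc4 at -0.76 ± 0.17, Aldh3a1 at -0.74 ± 0.18 and Tes at -1.18 ± 0.30. Each had an adjusted p of 0.985. Mtor, the drug's target, stood at -0.19 ± 0.25, Ddit4, an inhibitor of mTOR signalling, at -0.28 ± 0.25 and Gstp1 at -0.37 ± 0.27. Limma called 0 of 14497 genes, with 483 at an unadjusted p under 0.05, where 725 would be expected by chance. The fits without moderation, with an intensity trend, on the 2 groups alone, after quantile normalization and after median centring called 0 genes too. Array quality weights called 1 and a background covariate, chosen after the data were seen, called 15, 11 higher and 4 lower. The groups did not overlap in 875 genes, 6% of all, where chance gives 10%. Without placebo animal 3, 2 genes passed, Cyp4a3 at 1.55 (adjusted p = 0.0459) and Dbp, a clock-controlled transcription factor, at -1.67 (adjusted p = 0.0211). Without rapamycin animal 3, 3 genes passed, Cyp2a2 at 1.38 ± 0.19 (adjusted p = 0.0147), Cyp3a23-3a1 with an adjusted p of 0.0213 and Inhbe at 1.17 ± 0.18 (adjusted p = 0.0213).

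Gene lists differed between the treatments only in tests that assume a small correlation between genes, and 1 animal decided most of them. With an estimated correlation the smallest adjusted p over the 27 lists was 0.37, and the smallest by fry, which asks whether the members move 1 way on balance, was 0.589. No member of any list passed over all genes. NRF2 targets stood lower in 22 of 22 members (1 fell adjusted over the list alone), with a median of -0.63 (camera adjusted p = 1.91e-12, and adjusted p = 0.37 with an estimated correlation). The median was -0.13 without rapamycin animal 3 and -0.95 without rapamycin animal 2. Slc7a11 stood at -1.63 ± 0.53 (standard error) and Nqo1 at -1.27 ± 0.45. Ribosomal protein genes, whose translation mTOR controls, stood lower in 65 of 66 (0 adjusted over the list alone; median -0.38, adjusted p = 5.27e-17, and adjusted p = 0.456 with an estimated correlation). That call was lost without rapamycin animal 3 (median -0.01, adjusted p = 0.167), and the median was -0.59 without rapamycin animal 2. Interferon-stimulated genes stood higher in 23 of 25 (0 adjusted over the list alone; median 0.50, adjusted p = 5.8e-07, and adjusted p = 0.456 with an estimated correlation). That call was lost without rapamycin animal 1 (median 0.08, adjusted p = 0.408), and the medians over the left-out animals ran from 0.08 to 0.93, the highest without placebo animal 3. Acute phase genes stood higher in 18 of 19 (0 adjusted over the list alone; median 0.35, adjusted p = 1.45e-07, and adjusted p = 0.37 with an estimated correlation). Itih4 stood at 0.77 ± 0.24 and Fga at 0.63 ± 0.20. Their call held with each animal left out, with medians from 0.18 without placebo animal 2 to 0.57 without placebo animal 3, and 0.54 without rapamycin animal 3.

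Among lists of hepatocyte functions in the 2 kinds of foci, the P450 list stood at a median of 0.25 (camera adjusted p = 0.0012; 3 rose adjusted over the list alone), with Cyp3a2 at 1.70 ± 0.52 (standard error) and Cyp2c11 at 1.45 ± 0.43. The call was lost without rapamycin animal 1 (0.09) or 2 (0.12), and the median was 0.57 without rapamycin animal 3. Mature hepatocyte genes stood at 0.17 (adjusted p = 0.00271; 0 adjusted over the list alone), with Agxt at 0.91 ± 0.24 and Pck1, of gluconeogenesis, at 0.91 ± 0.29. Without rapamycin animal 3 that median was 0.53, and the call was lost without rapamycin animal 1 (0.04), rapamycin animal 2 (-0.04) or placebo animal 2 (0.09). The mTOR pathway components stood at -0.21 (adjusted p = 0.00271; 0 adjusted over the list alone), with Rheb, the activator of mTOR, at -0.47 ± 0.30 and Eif4ebp1, a translation repressor it phosphorylates, at -0.25 ± 0.19. Calls lost without rapamycin animal 3 were those of mTOR components (0.04 without it), autophagy (-0.22, and 0.10 without it), stellate cell and matrix (-0.27, and -0.02 without it) and macrophage genes (-0.31, and -0.08 without it). The calls of glycolysis (-0.16, and -0.02 without it), lymphocyte (0.17, and 0.03 without it) and cell cycle genes (-0.12, and -0.06 without it) and of focus markers (mean -0.23, and an adjusted p of 0.197 without it) were lost as well. Leaving out placebo animal 3 also ended the macrophage (-0.07), mTOR (-0.11), glycolysis (-0.04) and cell cycle calls (0.00). The cell cycle call was lost without placebo animal 2 (adjusted p = 0.0587) and rapamycin animal 2 (-0.07) too, and the lymphocyte call without placebo animals 1 (adjusted p = 0.122) and 2 (adjusted p = 0.0519). Biliary markers passed at an adjusted p of 0.0157, lost without placebo animal 2 or rapamycin animals 1 or 2. The cholesterol (0.08, adjusted p = 0.163) and fatty acid synthesis lists (0.12, adjusted p = 0.566) were not called, with medians of 0.51 and 0.53 without rapamycin animal 3. The ATF4 list had a median of 0.03 and a mean of -0.04 (adjusted p = 0.817).

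Whether rapamycin brought the foci nearer to normal liver was measured as the correlation of each animal's profile, across genes, with the mean normal liver. Over all 14497 genes, which are not independent replicates, Pearson's r was 0.949 ± 0.0396 (SD, n = 3) in rapamycin foci and 0.955 ± 0.0048 (SD, n = 3) in placebo foci, a difference of -0.0064 (2-sided exact permutation test, p = 1, where 3 against 3 animals cannot go below 0.1). Rapamycin animals 1, 2 and 3 stood at 0.971, 0.972 and 0.903 and the placebo animals at 0.950, 0.957 and 0.959. Without rapamycin animal 3 the difference was 0.0165. Over the 725 most variable genes, r was 0.775 ± 0.005 (SD) in rapamycin foci and 0.665 ± 0.04 (SD) in placebo foci. The difference was 0.110. Each of the 3 rapamycin animals (0.78, 0.774 and 0.77) lay above each of the 3 placebo animals (0.65, 0.71 and 0.635). The 2-sided exact permutation test on these values gave p = 0.1, the smallest that 3 against 3 animals allow. In rapamycin animal 3 the 60 genes at least 4-fold higher in placebo foci had a median log2 deviation of -1.54. Its r of 0.77 alone therefore does not show that its foci were nearer to normal liver.

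Changes against the same normal livers were shared between the treatments. Of the genes called in placebo foci, 750 were called in the same direction in rapamycin foci, 174 higher and 576 lower, and 0 in opposite directions, where independent lists would share 45.1. With AAF/PH liver, placebo foci shared 890 calls, 221 higher and 669 lower, and 10 ran in opposite directions, where independent lists would share 128.3. In 20 simulations of unchanged groups against shared controls 0 calls were shared, but unchanged groups give next to no calls, so this value does not measure how many shared calls the common controls bring about. The fold changes correlated across genes at r = 0.887 for rapamycin foci and 0.745 for AAF/PH liver, against a simulated 0.502, and their covariances were 0.242 and 0.28 against a simulated 0.028, which leaves 0.214 and 0.252. Part of the shared calls can come from the shared controls, since 3 normal livers cannot be split. Genes called lower in all 3 comparisons with normal liver numbered 520 and genes called higher 96.

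The arrays of rapamycin animal 3 stood apart. Across genes the root mean square log2 difference to its group was 0.712 to 0.794, against 0.238 to 0.422 in the 10 other pairs of animals within a group. Its 3 arrays lay 0.301 to 0.354 from each other, including the array of the second laser capture, and 0.665 to 0.86 from the arrays of the other rapamycin animals. Over the 725 most variable genes it formed a cluster of its own when 4 clusters were drawn. Gstp1 stood at 1615.4, 1649.8 and 2240.6 on its arrays, against 3743.4 to 4639.3 in the other foci and 100.07 to 115.51 in normal liver, and Akr1b8 at 179.5 against 762.8 to 1336 in the other foci. The 1104 olfactory receptor genes probed, which liver is not expected to express, had a median intensity of 9.24 in this animal. Their median was 5.84 to 7.65 in the 11 others.

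**Figure D3:**
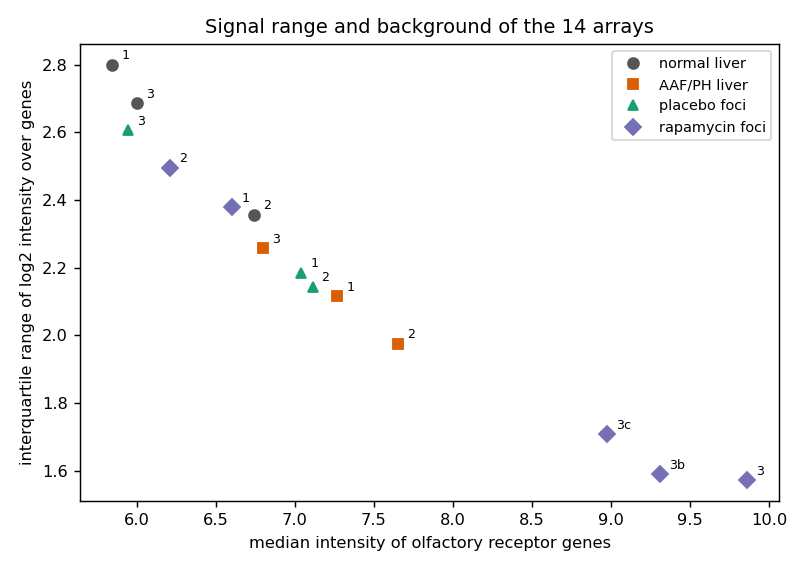
Interquartile range of log2 intensity over genes (y axis, log2 units) against the median intensity of 1104 olfactory receptor genes (x axis, array intensity) for the 14 arrays, coloured by group. The 3 arrays of rapamycin animal 3 lie apart from the others, with interquartile ranges of 1.57 to 1.71 and receptor medians of 8.97 to 9.86.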

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

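The residual correlations with animals other than normal liver animal 2, and the tests of a fault of 1 array, of surrounding normal liver, of the signal range and chance in rapamycin animals 1 and 2, and of the time of day of treated and normal rats were chosen only after the results were seen. In the test of level-dependent signal loss the outcomes were written down first, but the level it used was changed from the mean of 8 other animals, which gave -0.694, to that of the placebo foci.

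Probe sets without a gene name numbered 13311 and were tested in the fit of every probe set, with p-values adjusted over all of them. Of these, 483 differed between placebo foci and normal liver, 293 higher and 190 lower, with probe set 10776209 at -3.95 (adjusted p = 1.55e-05). Between AAF/PH liver and normal liver 1281 differed, 750 higher and 531 lower, with probe set 10887004 at 6.14 ± 0.60 (standard error, adjusted p = 3.35e-05) and probe set 10727438 at -5.54 ± 0.28 (standard error, adjusted p = 2.16e-07). What these probe sets measure was not analysed here.

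Rapamycin animal 3 held less Gstp1, Akr1b8 and Nqo1 than the other foci, and its deviation followed the level of a gene at r = -0.722 across genes, 59.5% of its variance. The outcome written down against loss of signal by level as the whole cause was met. The 60 genes at least 4-fold higher in placebo foci kept a median residual of -0.333, outside the -0.137 to 0.161 of 10000 random lists. Those lists were drawn gene by gene, matched on level only, and do not hold the joint variation of genes that move together. The 73 genes at least 4-fold lower had a median residual of -0.188, on the same side. The test therefore does not exclude loss by level as the whole cause. The residuals of this animal correlated across genes with those of normal liver animal 2 at 0.438. They also correlated with those of placebo animal 2 at 0.374 and AAF/PH animal 2 at 0.271. All of these were the animals of narrowest signal range in their groups. Placebo animal 1, which was not the narrowest of its group, stood at 0.255. Normal liver animals 1 and 3 stood at -0.398 and -0.12, AAF/PH animals 1 and 3 at -0.012 and -0.277, and placebo animal 3 at -0.518. Each deviation was taken from the other animals of the same group, so the values within a group are not independent. The positive values go with a signal loss by gene that is not particular to normal liver animal 2. A fault of 1 array was excluded, since the 3 arrays of rapamycin animal 3 lay at most 0.354 from each other. Surrounding normal liver was excluded as the whole cause. The same 73 genes had a median deviation of -0.658, where the share of 57.2% implied by Gstp1 would give 1.28. That share takes the whole drop of Gstp1 as admixed liver, and the deviation also holds the loss by level. A smaller share of normal liver beside a loss of signal therefore stays open. A real difference between lesions or in the response to the drug was not tested and stays open.

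Rapamycin animals 1 and 2 lay above the placebo animals in mature hepatocyte genes, with medians of 0.483 and 0.685 relative to the placebo mean against -0.07, -0.138 and 0.247, while rapamycin animal 3 stood at -0.36. The interquartile ranges of rapamycin animals 1 and 2 were 2.378 and 2.495, against 2.185, 2.144 and 2.606 in placebo animals 1, 2 and 3. A wider signal range was excluded as the whole cause. After quantile normalization the lower of the rapamycin animals 1 and 2 still lay 0.257 above the highest placebo animal, more than the placebo standard deviation of 0.128. That step gives the arrays a common distribution and cannot remove a signal loss by gene, which stays open. Chance stays open, since the difference of 0.571 gave p = 0.2 in a 2-sided exact permutation test of 2 against 3 animals, where the design allows no less than 0.1.

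Clock genes of both arms differed between treated and normal rats, and the genes were chosen after their values were seen. The mean of 6 genes of the Dbp arm minus 5 genes of the opposite arm was -1.759 ± 0.265 (SD, n = 3) in normal liver and 0.768 ± 0.681 (SD, n = 3) in placebo foci, a difference of 2.526. In rapamycin foci it was -0.075 ± 0.196 (SD, n = 3) and in AAF/PH liver 0.272 ± 0.192 (SD, n = 3). A different time of day at killing and a changed clock in the tissue, in phase or in level, would give the same values, and the labels hold no time. Between rapamycin and placebo foci the difference was -0.843 (2-sided exact permutation test, p = 0.2, smallest possible 0.1), with -0.485 in the Dbp arm and 0.357 in the other. The outcome written down against a different time of day was met, since placebo animal 3 lay among the rapamycin animals, but only by 0.126, less than the standard deviation within groups of 0.501, so it stays open.

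Other splits of the same 6 animals into 3 and 3 number 10 per comparison, the real one included, too few for a share under 0.05. In rapamycin foci against placebo foci the real split gave 0 genes and 10 of 10 splits gave at least as many, the highest 968, with placebo animals 1 and 2 and rapamycin animal 3 on 1 side. This points to a structure of the samples other than the treatment, and that split followed the signal range of the arrays. The interquartile range over genes was 2.185, 2.144 and 1.608 in placebo animals 1 and 2 and rapamycin animal 3. It was 2.606, 2.378 and 2.495 in placebo animal 3 and rapamycin animals 1 and 2. The side of narrower range also held the higher medians of olfactory receptor genes. Whether signal range or background brought about the 968 calls was not tested. In each of the other comparisons 1 of 10 splits, the real one, gave as many genes, and the highest other gave 0. The real counts were 1192 for placebo foci, 947 for rapamycin foci and 2900 for AAF/PH liver over normal liver. They were 608 and 581 for placebo and rapamycin foci over AAF/PH liver. Every other split mixes the groups compared, so a difference between the groups enters the spread. The 0 calls therefore do not measure what chance would give.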

How the results depend on the processing

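Chosen only after the results were seen were the background covariate, quantile normalization without rapamycin animal 3 and leaving that animal out of the shared spread. Counts are of called genes, named by the groups compared. For rapamycin against placebo foci the count stayed at 0 except with array weights (1) and the background covariate (15), and over left-out animals it ran from 0 to 3. For placebo foci against normal liver it was 718 without moderation, 2297 with only those groups, 6443 with array weights, 756 at 2-fold, 2598 with the covariate, 2291 by quantile normalization without rapamycin animal 3, 2462 with that animal out of the spread, and 606 to 1106 over left-out animals. For rapamycin foci against normal liver it was 289 without moderation, 210 with only those groups, 566 at 2-fold, and 224 to 2051 over left-out animals. For AAF/PH against normal liver it was 5115 with only those groups, 7996 with array weights, 1558 at 2-fold, 5208 with rapamycin animal 3 out of the spread, and 1552 to 2717 over left-out animals. For placebo foci against AAF/PH liver it was 1040 by quantile normalization, 399 by centring, 252 without moderation, 1334 with only those groups, 2011 with weights, 1753 with the covariate, 2102 and 1739 without rapamycin animal 3 in the normalization and in the spread, and 330 to 448 over left-out animals. For rapamycin foci against AAF/PH liver it was 1161, 375, 276, 204, 1264 and 2048 in the same order up to the covariate, 2162 by quantile normalization without rapamycin animal 3, and 297 to 2058 over left-out animals. The higher share moved with the covariate, to 48.6% in rapamycin foci and 51.8% in AAF/PH against normal liver, and to 47.5% in placebo foci against AAF/PH liver. Array weights ran from 0.009 for rapamycin animal 1 to 7.848 for normal liver animal 3, so counts with them rest on few arrays. Animals of the same number did not pair, since 18 such pairs correlated at -0.681 to 0.381 and the 36 others at -0.481 to 0.626, and with the number as a block the counts were 0, 919, 555, 2279, 429 and 418 in the order above. Over the most variable genes the similarity difference was 0.1099 and the mean distance of the arrays of rapamycin animal 3 from those of the other rapamycin animals went from 0.775 to 1.333. Shared calls fell to 415 and 238 at an adjusted p under 0.01 and to 533 and 460 at 2-fold, for AAF/PH liver and rapamycin foci with placebo foci. Of 8169 comparisons of named called genes 7497 kept the call, 672 lost it and 0 reversed, and of 5773 of uncalled ones 506 gained it. Of 2673 comparisons of lists 2288 were kept, 269 lost, 116 gained and 0 reversed. In comparisons without rapamycin foci, leaving rapamycin animal 3 out of the shared spread changed no group difference. The spread of this animal therefore lowered those counts. They were 1192 with it and 2462 without it for placebo foci and 2900 and 5208 for AAF/PH against normal liver. For placebo foci against AAF/PH liver they were 608 and 1739. Signal over background limits arrays, and the cause of the other changes was not tested.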

Other observations

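The genes and values of these paragraphs were chosen only after the results were seen. Some genes of MHC class II were among the largest rises common to all 3 comparisons with normal liver, though no list of such genes was tested. Cd74, the chaperone of MHC class II, rose by 2.06 in placebo foci, 2.05 in rapamycin foci and 2.24 in AAF/PH liver (log2), and the class II genes RT1-Bb, RT1-Da and RT1-Ba rose by at least 1.86, 1.82 and 1.70. Krt19, a keratin of bile ducts, rose by 2.46, 1.77 and 1.96 in the same order and Gpx2, a glutathione peroxidase of epithelia, by 3.63, 2.47 and 1.71. Anxa2 and the metal-binding protein gene Mt1 also rose in all 3. Aox3, Stac3, Inmt and Dhrs7l1 were the only genes at least 8-fold lower in all 3, and 0 genes were 8-fold higher in all 3.

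Interferon-stimulated genes varied between animals of the same group. Isg15, a ubiquitin-like antiviral protein, stood at 399.1 in rapamycin animal 1, 104 in rapamycin animal 2, 68.67 in rapamycin animal 3 and 125.4 in placebo animal 3, and at 35.79 and 33.14 in placebo animals 1 and 2. Normal livers held 63.58 to 69.96. Irf7, which amplifies the interferon response, stood at 240.2 in rapamycin animal 1 and 113.5 in placebo animal 3. The haemoglobin gene Hbb stood at 957.9, 467.5 and 1092 in normal livers and at 263.4 to 355.1 in all other animals, while the erythroid list was not called against normal liver (adjusted p = 0.166, 0.223 and 0.147 for placebo foci, rapamycin foci and AAF/PH liver). In AAF/PH liver the markers of other cell types did not rise alike, as a lower share of hepatocytes alone would have them do. The median of stellate cell and matrix genes lay 1.016 to 1.623 above that of endothelial genes in these animals, and mature hepatocyte genes fell unevenly, with quartiles of -1.69 and -0.521. A changed mix among the other cell types could give such a gap too. These values do not tell a change in the mix of cells from a change within cells.

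Core clock genes differed between placebo foci and normal liver in both arms. Bmal1 stood at -1.86 ± 0.31 (standard error, limma adjusted p = 0.0016), Npas2, its relative, at -1.65 ± 0.20 (adjusted p = 0.000141), Cry1, a repressor, at -1.78 ± 0.22 (adjusted p = 0.000189) and Nfil3 at -1.61 ± 0.24 (adjusted p = 0.000819). In the other arm Dbp rose by 1.81 ± 0.30 (adjusted p = 0.00166), Per3 by 1.07 ± 0.20 (adjusted p = 0.00377) and Nr1d2 by 0.70 ± 0.17 (adjusted p = 0.0165), and Nr1d1 passed with an adjusted p of 0.000928. Clock (-0.88, adjusted p = 0.093), Tef (0.25, adjusted p = 0.501) and Per2 (-0.09, adjusted p = 0.867) did not pass. Bmal1, Npas2, Cry1 and Nfil3 also passed in rapamycin foci and AAF/PH liver against normal liver. The Dbp arm was less uniform there. Dbp passed in neither (limma adjusted p = 0.21 and 0.124). Nr1d1 passed in rapamycin foci only (adjusted p = 0.0208, and 0.14 in AAF/PH liver). Per3 and Nr1d2 passed in AAF/PH liver only (adjusted p = 0.00289 and 0.0219, and 0.104 and 0.11 in rapamycin foci).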
